A study of Gallus gallus with 27 samples.

How the data were processed

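Total RNA from 27 chicken cell libraries was sequenced as paired-end reads after library construction with the NuGEN Trio kit, per the labels. Bowtie2, RSEM and DESeq2 and the build galGal6 are named in the labels, without versions or roles. The first deposited table holds counts of reads per Ensembl gene for 24356 genes in the 12 libraries of CEF2, CEF4, SCF2 and SCF4. It gives no gene names, so its genes were counted and not named. The second deposited table holds a signal per gene symbol for 14161 rows in all 27 libraries. Its name says TPM, but each column sums to 8.03 to 15.87 M (mega), and in the lowest library 100% of the rows are whole multiples of 1 value per library within a tolerance of 0.01. The deposited signal was therefore read as reads divided by 1 factor per library and is called normalized reads. How the authors set those factors is not stated. Because the table had been expected to hold TPM, the filters and pseudocount fixed before the data were examined were applied to normalized reads. The gene lists had been planned on the deposited counts for the first set, but those have no gene names, so all lists used the normalized reads. In 17 rows the symbol had been turned into a date, and these were kept without a name. The authors also deposited log2 fold changes and p-values (p-value and adjusted p-value) of their comparison of primary and suspension cells for 6424 genes per line. The direction is not stated in those tables and was read from their correlation with the values here.

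Groups were taken from the sample titles, and per the series design there were 3 biological replicates per group. The replicate numbers do not pair libraries of different groups, as tested by correlating residuals between equal numbers, so comparisons were unpaired. The labels of SCF2 and SCF4 give opposite breeds in the source name and the breed field, and groups were not changed for it.

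For the comparisons within the first set, edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr) was fitted to the deposited counts of the 12 libraries with a mean per group. The line difference was the contrast of the change in line 4 minus that in line 2. All other comparisons, all named genes and all gene lists used limma 3.58.1 (eBayes with trend and robust) on log2 of the normalized reads plus 1. Genes with 1 or more in at least 3 of the fitted libraries were kept. SDF1 against DF1 was fitted with CF2 and CF4, FAT against CF4 with CF2, and the comparisons of CF with CEF or SCF on all 6 groups. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

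Named genes followed a rule fixed before the data were examined. For SCF against CEF it took named genes called in both lines in the same direction, with a mean of 10 CPM or more of the recovered reads in the higher group of each line and no overlap between libraries. The 8 risen and 8 fallen with the largest smaller change were named, leaving out genes with only a LOC number. Other comparisons took the largest changes by the same criteria, 8 and 8 or 5 and 5. Up to 4 members with the smallest p-value were named in each gene list described, and 28 genes of interest were chosen besides. All of these but VIM, PDGFRA, THY1, CDH1 and CCN2 were listed in the plan beforehand. In all, 34 gene lists were also fixed beforehand, and those described were chosen after their results were seen. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists of a comparison, with an estimated correlation and fry as alternatives. Members were also adjusted over the list alone. The overlap of the lines was compared with the product of the called counts divided by the genes tested. A fold against a group without a read is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads over a group no fold is given.

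Depth came to 23.4 to 53.4 M reads per library in the count table and to 4.6 to 28.7 M recovered reads in the normalized table. One read equals 0.294 to 0.725 normalized reads in the cultured groups and 1.521 to 3.162 in FAT. The methods were tested on simulated data with 3 libraries per group. Of genes changed 4-fold, 98.5% to 100% were called in every comparison. Of genes changed 2-fold, 89.6% to 98.5% were called, except 55.2% and 56.7% for the line difference. The simulation gave every gene the same fixed spread and changed only a small part of the genes. Real replicates scattered unequally, with a correlation of log2 values from 0.907 in FAT to 0.998 in SDF1. The shares called in the simulation therefore need not hold for these data.

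The alternatives were RLE normalization and DESeq2 1.42.0 on the counts, no filter and a stricter filter of 10, a pseudocount of 0.1, quantile normalization, a replicate block, fitting only the groups compared, a minimum log2 change of 1 for the overlap, and leaving out each replicate in turn. The edgeR test on the recovered reads was added after the data were seen, and so were the block, quantile and leave-one-out settings for the gene lists. With it 8165 genes were called in SCF2 against CEF2, 8090 in SCF4 against CEF4 and 5617 in SDF1 against DF1. CCN2, which was among the 28 genes, has no row under that symbol in the normalized table and was not analysed here. Some further genes and gene lists are not reported here. Genes named in the closing section for DF1 replicate 3 and for the set of 25 genes were chosen after their values were seen. Read length, culture temperature and further breed details were left out of the parameters because no value in the tables rests on them.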

Results

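RNA was sequenced from 27 libraries of chicken (Gallus gallus) samples in 9 groups of 3 biological replicates each. CEF2 and CEF4 were primary embryonic fibroblast cultures, labelled Broiler Ross 308 and Israeli Baladi respectively. SCF2 and SCF4 were spontaneously immortalized lines grown in suspension without anchorage. CF2 and CF4 were immortalized lines grown attached. DF1 is an established chicken fibroblast line, and SDF1 was its anchorage-independent form. The last group was labelled Fat and is called FAT here, and whether it was tissue or cells differentiated in culture is not given in the sources used here. The labels of SCF2 and SCF4 gave opposite breeds in 2 of their fields, so line 2 and line 4 are named by number only. The 12 CEF and SCF libraries formed a first deposited set and the other 15 a second set.

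The deposited count table held 23.4 to 53.4 M (mega) reads per library for the 12 libraries of the first set. The normalized table covered all 27 libraries, and the reads recovered from it came to 12.3 to 28.7 M in the cultured groups and 4.6 to 10.4 M in FAT. Gene values below are normalized reads from that table, as mean ± SD with n = 3, and log2 fold changes are from a limma fit to it. Counts of called genes in the first set are from edgeR on the deposited counts. Intervals and floors cover counting error only. P-values rest on the spread between libraries within groups, pooled per gene over all groups of a fit, not between separately derived lines. Replicates correlated at 0.996 to 0.997 in CF2 and CF4, 0.95 to 0.994 in DF1 and 0.907 to 0.953 in FAT. Since CF2 and CF4 were in the fits of SDF1 against DF1 and FAT against CF4, p-values there can be too small. Quantile normalization moved the median change of all genes by over 0.1 in several comparisons. That median went from -0.076 to 0.221 in SCF2 against CEF2, from -0.042 to 0.167 in SCF4 against CEF4, from 0.083 to -0.051 in SDF1 against DF1 and from 0.398 to -0.237 in FAT against CF4. It went from -0.176 to 0.207 in CF2 against CEF2 and from -0.108 to 0.155 in CF4 against CEF4. In the limma fit the share of called genes that rose went from 44.5% to 59.5%, 47.4% to 57.5%, 57.4% to 46.6%, 61.2% to 43.5%, 41% to 58.7% and 44.4% to 57.4% in the same order. For CEF4 against CEF2 it went from 42.7% to 52% and for the line difference from 56% to 48.7%. In SCF2 against CF2 it went from 58% to 50.2% and in SCF4 against CF4 from 59.7% to 51.5%. Counts of rises and falls therefore depend on the scaling, and the directions of single genes below are given with quantile normalization where it changed them.

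**Figure D1:**
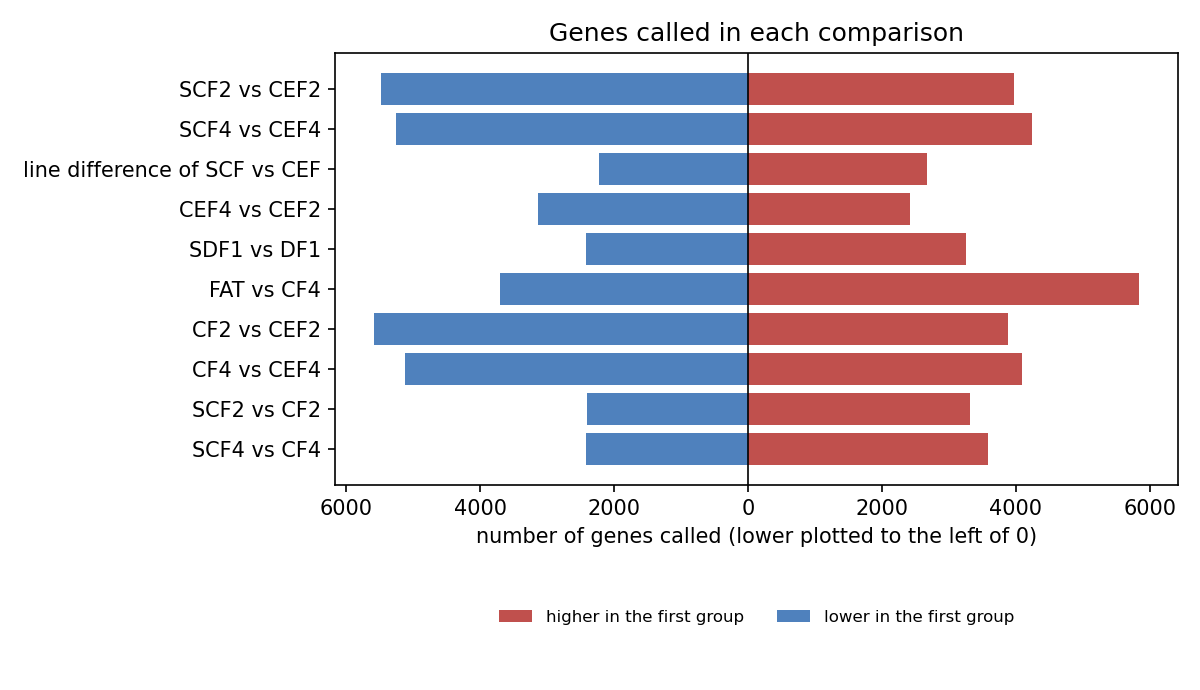
Number of genes called in each comparison, with genes higher in the first group to the right of 0 and genes lower in it to the left. The horizontal axis is a count of genes. SCF2 vs CEF2 had 3972 higher and 5485 lower, and CEF4 vs CEF2 had 2423 and 3140.

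The comparison of suspension lines with primary cultures asks what distinguishes an immortalized, anchorage-independent line from the primary fibroblast culture of the same number. Most matrix genes were lower in both suspension lines, and most contractile genes were lower too, with smaller changes in line 4. LOX, which encodes the enzyme that crosslinks collagen and elastin, was 5910 ± 832 in CEF2 and 8790 ± 462 in CEF4 and had no read in SCF2 or SCF4, at least 12200-fold and 19400-fold lower against a floor of 3 reads over the group. ACTA2, smooth muscle actin, fell from 84600 ± 2500 to 839 ± 106 in line 2 and from 17900 ± 1070 to 1160 ± 143 in line 4. CDKN1A, the cell cycle inhibitor p21, fell from 1710 ± 212 to 28.7 ± 7.62 and from 2230 ± 520 to 31 ± 6. CDKN2A rose from 424 ± 70 to 3260 ± 506 and from 1720 ± 334 to 4420 ± 932.

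In SCF2 against CEF2, 9457 of 14471 tested genes were called, 3972 higher and 5485 lower. In SCF4 against CEF4, 9509 were called, 4245 higher and 5264 lower. Of these, 6563 were called in both lines in the same direction. Independent lists would share 3160, and 580 went in opposite directions where 3054 would by chance. Across the 14471 genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.768. In the normalized reads the group means of SCF2 and SCF4 correlated at r = 0.981, and with SDF1 at 0.973 and 0.975. With the CEF groups they correlated at 0.837 to 0.848. The overlap was therefore not separated from a profile common to the immortalized groups.

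Among the genes that rose most in both lines, KRTAP10-4 rose by 9.10 ± 0.40 (log2, SE; adjusted p = 9.46e-11) in line 2 and by 10.19 ± 0.40 (adjusted p = 2.72e-11) in line 4. The other 7 were CBLN2, SKAP1, MCTP1, APCDD1, PTPRE, TEKT5 and MPZL2, with log2 changes of 6.19 to 8.25 in line 2 and 6.55 to 11.45 in line 4. APCDD1, a membrane-bound inhibitor of Wnt signalling, went from 34.2 ± 2.9 to 3980 ± 470 and from 5.51 ± 2.86 to 4350 ± 614. The 8 that fell most were LOX, SLC16A1, COL8A2, FIBIN, FBLN1, LSP1P1, SPP1 and FSCN1. FBLN1, a matrix glycoprotein gene, was 1770 ± 79.2 in CEF2 and 1980 ± 43.5 in CEF4 and had no read in either suspension line, at least 3670-fold and 4380-fold lower. SPP1, which encodes osteopontin, was 3390 ± 303 and 3590 ± 842 in the primary cultures, at least 7010-fold lower in SCF2, which had no read, and 1.48 ± 0.219 in SCF4.

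Of 52 measured genes for collagens and matrix, 3 rose and 43 fell in line 2 and 3 rose and 46 fell in line 4, the same counts as when adjusted over the list alone. The medians were -3.90 and -3.92 (camera adjusted p = 5.76e-13 and 4.53e-17), also with genes at 0 in a whole group set to their bound, and -3.35 and -3.42 after quantile normalization. COL12A1 changed by -10.5 and -9.07, and TGFBI changed by -10.87 and -8.43 in line 2 and line 4. Of 26 contractile and smooth muscle genes, 1 rose and 24 fell in line 2 and 3 rose and 17 fell in line 4, likewise when adjusted over the list alone. The camera adjusted p was 2.29e-09 in line 2 and 0.000528 in line 4, where the adjusted p = 0.055 with an estimated correlation. The median of these genes was -3.82 in line 2 and -1.18 in line 4. TAGLN changed by -8.12 and -6.48, TPM1 by -5.01 and -3.41 and CALD1 by -5.61 and -6.77. Of 23 skeletal muscle markers, 0 rose and 22 fell in line 2 (median -6.42, camera adjusted p = 5.28e-09) and 5 rose and 7 fell in line 4 (median -0.06, camera adjusted p = 0.548), also when adjusted over the list alone. Of 15 cartilage and bone markers, 2 rose and 11 fell in line 2 (median -7.25, camera adjusted p = 2.50e-05) and 2 rose and 13 fell in line 4 (median -10.46, camera adjusted p = 6.58e-07), also when adjusted over the list alone. Whether the falls reflect the cell types of the primary cultures was not tested.

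Genes of the cell cycle moved the other way. Of 57, 54 rose and 2 fell in line 2 and 50 rose and 2 fell in line 4, against 54 and 3 and 50 and 2 when adjusted over the list alone (camera adjusted p = 1.11e-13 and 2.11e-11). PRC1, which bundles microtubules at the end of mitosis, rose from 452 ± 25.2 to 2470 ± 99.1 and from 616 ± 83.2 to 2180 ± 238. BUB1B rose by 1.93 and 1.75, KIF23 by 2.29 and 1.77 and TPX2 by 1.5 and 1.64.

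**Figure D2:**
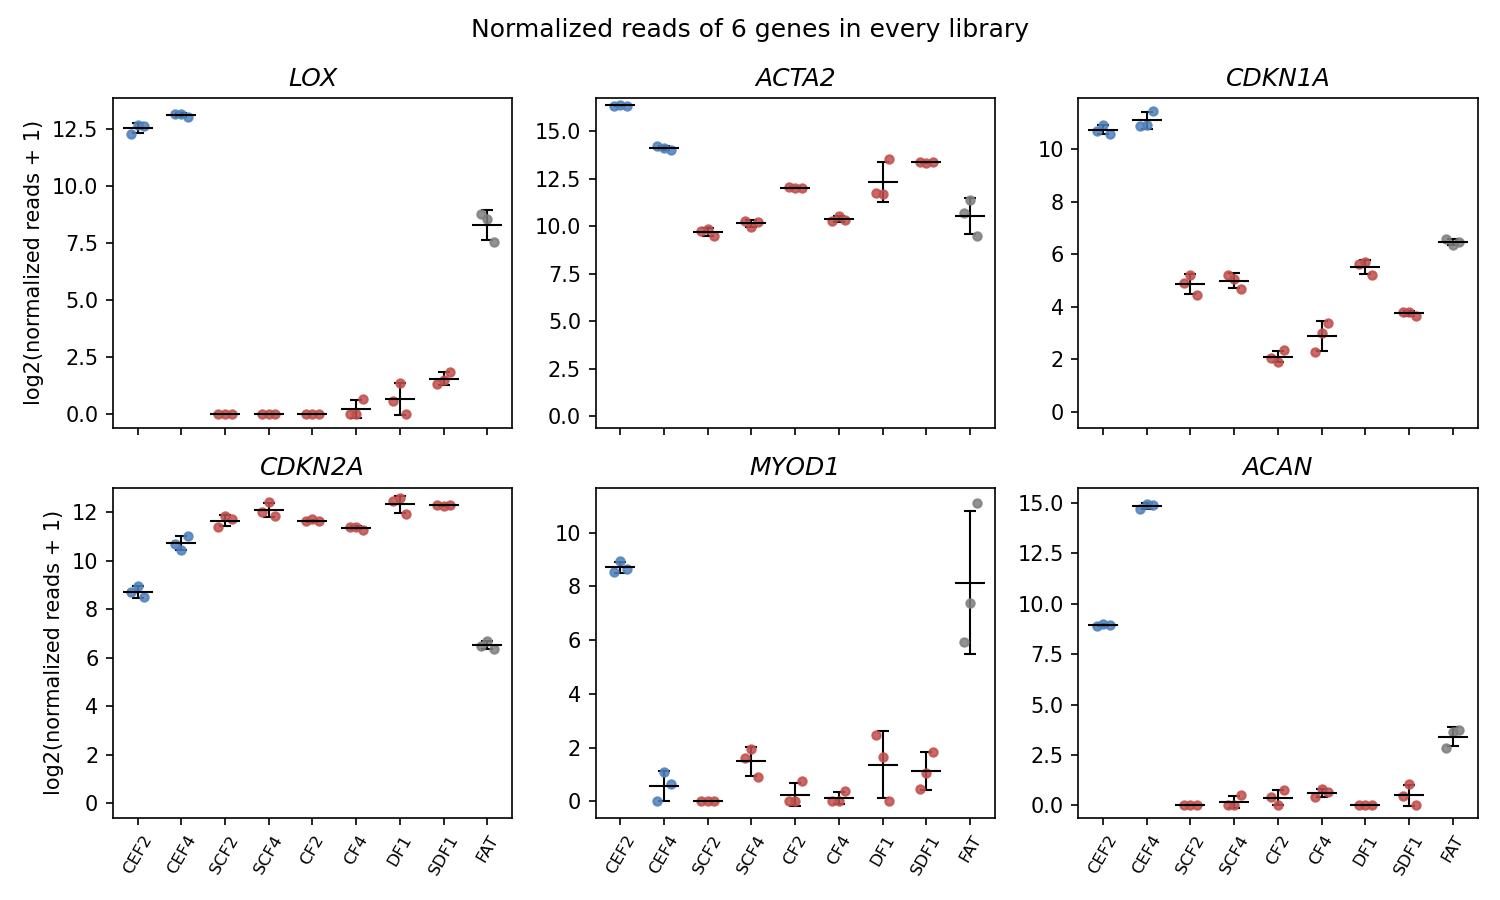
Normalized reads of LOX, ACTA2, CDKN1A, CDKN2A, MYOD1 and ACAN in each library, as log2 of the value plus 1 on the vertical axis, by group on the horizontal axis. Points are libraries, and bars are the mean and SD of the 3 replicates on the log2 scale. CDKN1A was 1710 in CEF2 and 28.7 in SCF2, while CDKN2A was 424 and 3260.

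Of 32 genes of the TGF-beta and BMP pathway, 3 rose and 24 fell in line 2 and 3 rose and 26 fell in line 4, against 4 and 24 and 4 and 26 when adjusted over the list alone (camera adjusted p = 6.72e-05 and 2.19e-05). TGFB2 went from 1730 ± 141 to 0.212 ± 0.367 and from 2930 ± 366 to 1.57 ± 1.25. TGFB3 changed by -3.41 and -2.07, FST by -9.44 and -7.26 and GREM1 by -6.62 and -6.61. Of 32 adipocyte genes, 2 rose and 27 fell in line 2 and 5 rose and 19 fell in line 4, against 2 and 29 and 5 and 19 when adjusted over the list alone (camera adjusted p = 3.10e-07 and 0.00438). LPL, the lipoprotein lipase gene, was 746 ± 61.9 in CEF2 and 217 ± 13.8 in CEF4 and had no read in SCF2, at least 1540-fold lower in line 2. ZNF423 changed by -6.43 and -6.50, G0S2 by -6.29 and -6.93 and FABP3 by -6.70 and -6.52. Of 38 genes for cadherins and cell-cell adhesion, 4 rose and 33 fell in line 2 and 6 rose and 25 fell in line 4, against 5 and 33 and 6 and 25 when adjusted over the list alone. The camera adjusted p was 2.14e-06 and 0.00153, but adjusted p = 0.0611 and 0.173 with an estimated correlation. ALCAM changed by -7.65 and -9.72, NECTIN1 by -7.56 and -7.33, CDH3 by -9.27 and -8.56 and NCAM1 by -10.42 and -8.00.

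**Figure D3:**
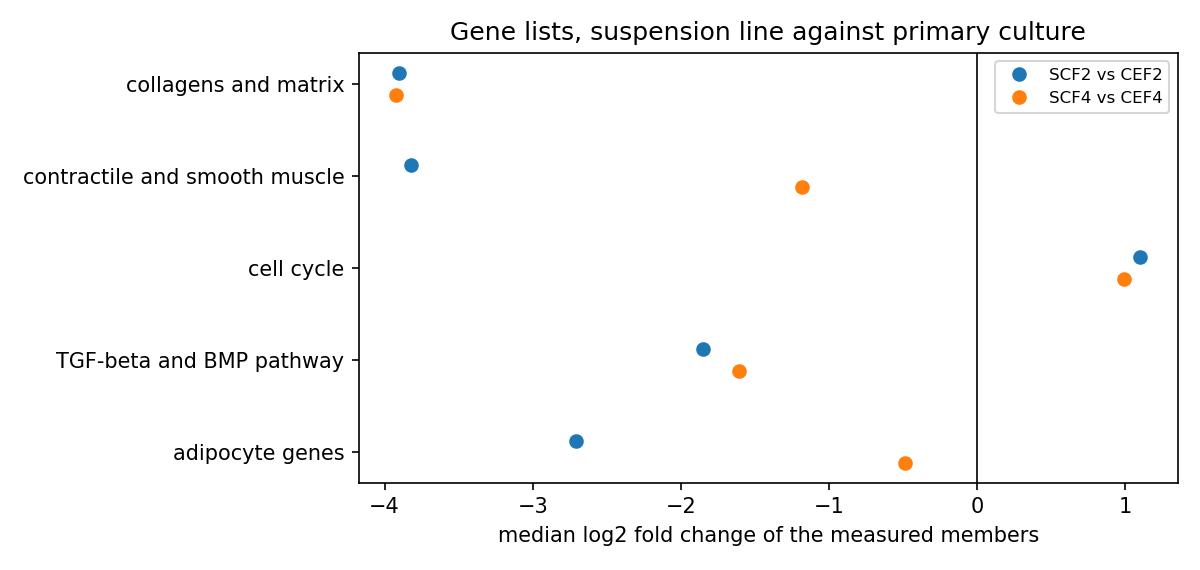
Median log2 fold change of the measured members of 5 gene lists in SCF2 vs CEF2 and SCF4 vs CEF4, with the median on the horizontal axis and 1 point per comparison. The median for collagens and matrix was -3.90 in line 2 and -3.92 in line 4, and that for the cell cycle 1.10 and 0.99.

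The genes of interest to immortalization, fat and adhesion were read in the same comparison. TERT, the telomerase reverse transcriptase gene, stayed at 2.77 ± 0.837 and 2.43 ± 1.62 in CEF2 and SCF2 and at 0.372 ± 0.322 and 1.03 ± 0.597 in CEF4 and SCF4. Its changes of -0.21 (adjusted p = 0.675) and 0.54 (adjusted p = 0.273) were not called at this depth, but after quantile normalization it was called higher in both lines, by 2.04 and 1.39. MDM2 changed by -2.35 and -2.68 and CDKN2B by -2.60 and -3.53. RB1 fell by 0.40 in line 2 and was not called in line 4 (-0.08). MKI67 rose by 1.49 in line 2 and was not called in line 4 (0.11). MYC was not called in line 2 (0.05) and fell by 0.74 in line 4. The adipogenic regulator PPARG changed by -4.65 and -2.86, FABP4 by -9.78 and -4.68 and PLIN2 by -1.46 and -0.28. The change of PLIN2 in line 4 was not called with only the groups compared in the fit (-0.28) or without SCF4 replicate 1, SCF4 replicate 3 or CEF4 replicate 1, at -0.28, -0.23 and -0.21. PPARGC1A was not called in line 2 (-0.61) and rose by 3.51 in line 4, where all CEF4 libraries were at 0, at least 20.8-fold higher. After quantile normalization it rose by 1.10 in line 2. FASN rose by 0.94 in line 2 and was not called in line 4 (-0.02). The test of the difference between the lines called MKI67, MYC, PPARGC1A and FASN but not RB1.

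COL1A1 changed by -2.43 and -3.34, COL1A2 by -4.63 and -4.84 and FN1 by -3.89 and -5.05. ITGB1 changed by -0.83 and -0.82, and after quantile normalization it was not called in line 4 (-0.19). VIM changed by -1.55 and -2.53 and CDH1 by -5.76 and -3.28, while CDH2 rose by 1.74 and 1.63 and CAV1 by 0.73 and 0.56. CDH11 changed by -10.26 in line 2 and by -2.23 in line 4. YAP1 changed by -0.34 and -0.65, but its call in line 2 was lost without SCF2 replicate 2, SCF2 replicate 3, CEF2 replicate 1 or CEF2 replicate 3, at -0.26, -0.28, -0.35 and -0.28, and with a replicate block (-0.34). PDGFRA was called in neither line (0.63 and 0.73). It was called in line 2 with only the groups compared in the fit (0.63), in line 4 without CEF4 replicate 3 (1.15), and in both lines after quantile normalization (1.07 and 1.83). THY1 was called in neither (0.13 and -0.06), but rose by 0.43 and 0.59 after quantile normalization. CCN2 was not analysed here, since the normalized table has no row under that symbol.

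The tables of the authors' own comparison held log2 fold changes for 6424 genes per line, with 4709 called in line 2 and 4567 in line 4. Across the 5609 and 5612 genes matched by symbol, they correlated with the suspension minus primary changes at r = -0.977 and -0.976. Their fold changes are therefore coded as primary minus suspension.

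Whether the change from primary culture to suspension line differed between the lines was tested as an interaction. Of 23 skeletal muscle markers, 19 had a higher and 0 a lower change in line 4 (camera adjusted p = 6.06e-12), and of 15 cartilage and bone markers 2 had a higher and 11 a lower one (camera adjusted p = 4.97e-07), also when adjusted over the list alone. MYOD1, the master regulator of skeletal muscle, was 419 ± 61.1 in CEF2 and 0.557 ± 0.553 in CEF4, and 0 and 1.94 ± 1.03 in SCF2 and SCF4. MATN3, a cartilage matrix gene, was 2.25 ± 0.497 in CEF2 and 898 ± 31.5 in CEF4 and had no read in either suspension line. PITX1, a hindlimb transcription factor gene, was lost in line 4 alone, from 309 ± 60 to 0.115 ± 0.198, against 212 ± 13.3 and 530 ± 109 in line 2. PCBP4 was lost in line 2 alone, from 547 ± 69.6 to 0.285 ± 0.494, against 142 ± 7.68 and 278 ± 39.8 in line 4.

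The difference was called for 4905 of 14471 genes, 2679 with a higher change in line 4 and 2226 with a lower one. Besides PCBP4 (9.75 ± 0.32, adjusted p = 1.58e-10) and MYOD1 (9.62 ± 0.50, adjusted p = 6.49e-09), the largest positive differences were for FGD5, NPY and MMP7, at 9.65, 9.43 and 9.19. The largest negative ones were for PAPPA2, PITX1, SLC6A17, CSGALNACT1 and MATN3, at -9.93, -9.41, -8.90, -8.15 and -8.12. With edgeR on recovered reads the difference of MATN3 was not called (adjusted p = 1), while its log2 value was -8.56. Of 22 genes of cholesterol synthesis, 0 had a higher and 19 a lower change in line 4, or 0 and 20 when adjusted over the list alone (camera adjusted p = 3.51e-10). INSIG1 differed by -2.58 and HMGCS1 by -1.09. Of 21 genes of the unfolded protein response, 0 were higher and 15 lower, also when adjusted over the list alone. The camera adjusted p was 6.39e-06, with adjusted p = 0.0596 with an estimated correlation. P4HB differed by -1.13, HERPUD1 by -1.48, DNAJB9 by -1.05 and HYOU1 by -0.95. Of the 26 contractile and smooth muscle genes, 21 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 7.49e-09). ACTA2 differed by 2.71, PDLIM3 by 6.12 and DES by 8.13. CRYAB differed by 7.04 and was not called with edgeR on recovered reads (11.18, adjusted p = 1).

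The primary cultures were compared with each other to describe how the cultures of the different numbers differ. Skeletal muscle markers were higher in CEF2 and cartilage markers in CEF4. MYOG, which drives muscle differentiation, was 266 ± 19.8 in CEF2 and had no read in CEF4, at least 514-fold lower. The cartilage proteoglycan gene ACAN was higher in CEF4 by a log2 change of 5.89 ± 0.18 (SE, adjusted p = 8.25e-11). COL9A2, a cartilage collagen gene, was 482 ± 49.3 in CEF2 and 25500 ± 5550 in CEF4, and HAPLN1 369 ± 11.3 and 8410 ± 1240. Of 23 skeletal muscle markers, 0 were higher and 19 lower in CEF4, or 1 and 20 when adjusted over the list alone (camera adjusted p = 3.57e-14). Of 15 cartilage and bone markers, 11 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 5.64e-09). In all, 5563 of 14471 genes were called, 2423 higher and 3140 lower in CEF4. MATN3, CHAD, C9H2ORF82, CYTL1 and NPTX2 rose most, by 8.12, 6.98, 6.96, 6.39 and 6.34. NPY, MMP7, TNNT2, MYOD1 and MYOG fell most, with changes of -9.29, -9.17, -8.81, -8.13 and -8.06, and MYL1 changed by -7.44. All 6 measured W-linked genes were higher in CEF4, with a median of 1.35, also when adjusted over the list alone (camera adjusted p = 2.32e-05, and adjusted p = 0.0104 with an estimated correlation). Whether the cultures differ in the sex of their embryos was not tested. Breed and culture cannot be told apart here, since each breed label had only 1 group of primary libraries.

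SDF1 was compared with DF1 to see what changes when an established attached line grows without anchorage. Amino acid response genes were higher in SDF1, but not called as a list with an estimated correlation (adjusted p = 0.0526). CHAC1, which degrades glutathione and is induced by amino acid stress, was 319 ± 11.8 in DF1 and 7580 ± 286 in SDF1. FOS, an immediate early transcription factor gene, was 51.8 ± 8.97 and 3210 ± 171. SYNPO2, an actin-binding protein gene, was 2.12 ± 0.581 and 166 ± 5.49. PLXND1, a semaphorin receptor gene, was 195 ± 8.63 and 1.83 ± 1.01. DF1 replicate 3 lay far from DF1 replicates 1 and 2, with DKK3 at 4.98 against 531 and 556, KRTAP10-4 at 2560 against 7.48 and 11.6 and CDH2 at 13100 against 2780 and 2690.

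In all, 5667 of 11834 genes were called, 3251 higher and 2416 lower in SDF1. Without DF1 replicate 3 the count was 8683, and with only the 2 groups fitted it was 3619. CKS1B, TUBB3, FOS, SYNPO2, S100A4, ADH1C, GSTA3 and CSF2RA rose most, by 4.94 to 6.64. COL8A1, FGD5, CDH5, PLXND1, CHMP4C, DKK3, EDNRB2 and PDZD2 fell most, with log2 changes of -6.47 to -5.51. DKK3 and PDZD2 were not called with only the 2 groups fitted (adjusted p = 0.0641 and 0.0644). S100A4 and GSTA3 were also among 25 genes higher in every CF library than in every CEF and SCF library. ATP8, another of these, was 16.71 to 17.37% of ATP6 in SDF1 and 1.1% and 1.22% in DF1 replicates 1 and 2, so a difference in library preparation cannot be told apart from growth without anchorage here. Of 26 amino acid response genes, 18 rose and 1 fell, or 19 and 1 when adjusted over the list alone. The camera adjusted p was 0.000905. SLC7A1, CEBPB and SLC38A2 rose by 1.89, 1.96 and 1.05. Of 21 heat shock genes, 4 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 0.00983, but adjusted p = 0.558 with an estimated correlation). HSPA8 changed by -1.76, HSPA4L by -0.96 and CHORDC1 by -0.70, while HSPB9 rose by 1.39. All 6 measured W-linked genes rose, also when adjusted over the list alone (camera adjusted p = 0.00983, but adjusted p = 0.42 with an estimated correlation). HINTW rose by 1.99, HNRNPKL by 1.23, SPIN1W by 1.07 and ATP5A1W by 2.65.

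Among the genes of interest, MDM2 rose by 1.21, CDKN2B by 3.68, PLIN2 by 0.47, COL1A1 by 2.41, COL1A2 by 1.32, PDGFRA by 2.88 and THY1 by 0.99 in SDF1. CDKN1A changed by -1.75, MYC by -2.59 and VIM by -1.38. Without SDF1 replicate 1, 2 or 3, VIM was not called (-1.38, -1.37 and -1.39), nor was it with only the groups compared (-1.38). ACTA2 rose by 1.03, but its call was lost without SDF1 replicate 1, 2 or 3 (1.03, 1.04 and 1.02) and without DF1 replicate 1 or 2 (0.74 and 0.72). It was also lost with no filter, a pseudocount of 0.1, a replicate block or only the groups compared (1.03 in each) and with edgeR on recovered reads (0.67). Not called were TERT (-0.84), CDKN2A (-0.05), RB1 (-0.39), MKI67 (0.04), PPARG (2.68), PPARGC1A (0.24), FASN (-0.79), FABP4 (0.42), FN1 (-0.33), ITGB1 (0.43), CDH2 (0.74), CDH11 (0.89), CAV1 (0.53), YAP1 (0.21) and CDH1 (-0.71). Without DF1 replicate 3, CDKN2A (-0.25), PPARG (0.91), FASN (-0.35), ITGB1 (0.79), CDH2 (1.5) and CAV1 (1.0) were called. Without DF1 replicate 1 or 2, PPARG (3.58 and 3.54) and FASN (-1.01 and -1.0) were called too. FASN was also called after quantile normalization or with a replicate block (-0.79 in each) and with edgeR on recovered reads (-1.01). CDH1 was called with a pseudocount of 0.1 (-2.38).

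FAT was compared with the attached line CF4, which has the same breed label. Most adipocyte, muscle, vessel and blood cell genes were higher in FAT, but none of these lists was called with an estimated correlation (adjusted p = 0.21, 0.678, 0.678 and 0.444). FAT replicate 3 stood apart, with r = 0.907 and 0.926 to replicates 1 and 2 against 0.953 between those, and held the most muscle transcripts. FABP4, the fatty acid carrier of adipocytes, was 140000 ± 89300 in FAT and had no read in CF4, at least 431000-fold lower. PLIN4, a lipid droplet coat gene, was 12200 ± 6150 in FAT and 0.638 ± 0.595 in CF4. PECAM1, an endothelial adhesion gene, was 12000 ± 6950 and 14.6 ± 3.42. MKI67, a proliferation marker, was 119 ± 35.1 in FAT and 2470 ± 189 in CF4. The skeletal actin gene ACTA1 was 14300, 50600 and 744000 in FAT replicates 1, 2 and 3, and 0.643 ± 1.11 in CF4, and MYL1 was 4350, 10200 and 128000 in the same FAT replicates.

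In all, 9552 of 12861 genes were called, 5844 higher and 3708 lower in FAT. APOA1, FABP4, ACTA1, COL4A1, MYL1, AKAP12, MGP and TNNT3 rose most, by 13.66 to 17. HINTW, KRTAP10-4, CCK, NDNF, DSG4, KIAA1644, AHRR and SLC39A8 fell most, with changes of -12.36 to -8.81. Of 34 adipocyte genes, 29 rose and 1 fell, and of 19 skeletal muscle markers all 19 rose. Of 16 endothelial markers, 14 rose and 2 fell, and of 23 blood and immune markers 21 rose and 0 fell. Of 57 cell cycle genes, 1 rose and 55 fell, and of 21 cholesterol synthesis genes 0 rose and 19 fell. The counts of all 6 lists were the same when adjusted over the list alone. Their camera adjusted p were 1.91e-06, 0.00043, 0.00236, 2.73e-06, 5.43e-23 and 2.77e-09 in that order. For the cell cycle the adjusted p = 0.000567 with an estimated correlation, while the other 5 had adjusted p = 0.21, 0.678, 0.678, 0.444 and 0.21 with an estimated correlation. CD36 rose by 9.96, PLIN4 by 12.82, MEF2C by 10.35, DES by 12.18, CDH5 by 9.98, KDR by 7.39, PECAM1 by 9.36 and SOX18 by 10.42. C1QA, C1QB, BLB2 and BLB1 rose by 9.65, 10.00, 11.88 and 11.55. GINS2 changed by -6.58, KIF20A by -4.90, NDC80 by -4.96, PRC1 by -6.42, CYP51A1 by -4.66, SQLE by -8.33 and MVK by -1.92. All 6 measured W-linked genes were lower in FAT, with a median of -4.99, also when adjusted over the list alone (camera adjusted p = 0.000488, but adjusted p = 0.132 with an estimated correlation). HINTW was 4.84 ± 8.38 in FAT and 13100 ± 452 in CF4, and ATP5A1W was 292 ± 308 and 1920 ± 56.1. SMAD7B had no read in FAT and was 52.4 ± 1.87 in CF4, and HNRNPKL was 18.5 ± 10.7 and 2310 ± 12.3. These values argue against FAT and CF4 coming from animals of the same sex. Any effect of sex cannot be told apart from the group here.

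Among the genes of interest, MDM2 rose by 0.70, CDKN1A by 3.59, PPARG by 4.87, PLIN2 by 1.87, COL1A2 by 2.66, CDH11 by 1.93, VIM by 1.76 and PDGFRA by 5.00 in FAT. CDKN2A changed by -4.85, CDKN2B by -5.22, RB1 by -0.89, MKI67 by -4.42, MYC by -1.44, FASN by -2.34 and CDH2 by -4.92. COL1A1 and FN1 rose by 1.74 and 1.02, but after quantile normalization neither was called (0.10 and 0.21). THY1 rose by 0.51, but fell by 0.69 after quantile normalization, and was not called without FAT replicate 1 or 2 (0.35 and 0.46) or CF4 replicate 1, 2 or 3 (0.49, 0.53 and 0.50), with only the groups compared (0.51) or with edgeR on recovered reads (0.22). TERT rose by 1.45, but was at -0.97 after quantile normalization and was not called without FAT replicate 1 or 2 (1.18 and 1.23) or CF4 replicate 1, 2 or 3 (1.21, 1.67 and 1.47), with only the groups compared (1.45) or with a pseudocount of 0.1 (2.19). CDH1 rose by 1.96, but was at -0.62 after quantile normalization and was not called without CF4 replicate 3 (1.64). ITGB1 fell by 0.55 and was not called without FAT replicate 2 (-0.60) or CF4 replicate 1, 2 or 3 (-0.56, -0.56 and -0.54), or with only the groups compared (-0.55). PPARGC1A (0.17), ACTA2 (0.16), CAV1 (-0.19) and YAP1 (0.03) were not called. Without FAT replicate 3, PPARGC1A fell by 1.0, and ACTA2 (0.67) and YAP1 (0.24) rose. Without FAT replicate 2, CAV1 fell by 0.59.

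The attached immortalized lines were compared with the primary cultures to separate immortalization from growth in suspension. Most matrix genes were lower in both attached lines. LOX was absent from CF2 and 0.196 ± 0.34 in CF4. TIMP3, a matrix-bound inhibitor of metalloproteinases, went from 9620 ± 375 to 161 ± 9.01 in line 2 and from 4160 ± 45 to 174 ± 18.6 in line 4. VIP, a neuropeptide gene, went from 11.1 ± 5.6 to 1360 ± 43.7 and from no read to 1290 ± 16.1, at least 2510-fold higher. VIP is 1 of the 25 genes higher in every CF library than in every CEF and SCF library. In CF2 against CEF2, 9473 of 13123 genes were called, 3880 higher and 5593 lower, and in CF4 against CEF4 9213, 4090 higher and 5123 lower. In both lines and the same direction were 6353, against 3393 expected of independent lists. KRTAP10-4, CBLN2, SKAP1, MCTP1 and VIP rose most, by 6.94 to 10.22 in line 2 and 7.44 to 11.71 in line 4. LOX, SLC16A1, COL8A2, FIBIN and FBLN1 fell most, and TGFBI changed by -11.37 and -8.93. Of 52 genes for collagens and matrix, 3 rose and 44 fell in line 2 and 3 rose and 49 fell in line 4, also when adjusted over the list alone (camera adjusted p = 4.92e-12 and 1.28e-16). Of 57 cell cycle genes, 50 rose and 1 fell and 48 rose and 3 fell, or 50 and 2 and 48 and 3 when adjusted over the list alone (camera adjusted p = 4.13e-14 and 1.50e-11). BUB1B rose by 1.77 and 1.40, KIF23 by 1.64 and 1.78, TPX2 by 1.46 and 1.47 and UHRF1 by 1.30 and 1.46. The CF libraries were all in the second deposited set and the CEF libraries in the first, so batch and group cannot be told apart for changes seen in CF alone. The falls of matrix genes and rises of cell cycle genes were also seen in SCF against CEF, within the first set.

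The suspension lines were compared with the attached lines to look for changes of growth without anchorage. SMOX, HSPB9 and SPTB were among the genes that rose most in suspension. SMOX, which encodes spermine oxidase, was 94.7 ± 8.56 in CF2 and 382 ± 40.4 in SCF2, and 87.7 ± 1.83 in CF4 and 360 ± 14.5 in SCF4. HSPB9, a small heat shock protein gene, was 55.3 ± 4.52 and 340 ± 37.8 in line 2 and 38.2 ± 3.36 and 584 ± 201 in line 4. SPTB, the spectrin beta chain gene, was 83.4 ± 7.98 and 576 ± 13.2, and 164 ± 8.43 and 754 ± 306. In SCF2 against CF2, 5713 of 13123 genes were called, 3312 higher and 2401 lower, and in SCF4 against CF4 6002, 3585 higher and 2417 lower. In both lines and the same direction were 2465, against 1347 expected of independent lists. SDF1 against DF1 shared 1609 same-direction genes with SCF2 against CF2 (1389 expected) and 1552 with SCF4 against CF4 (1469 expected). In opposite directions were 1302 (1327 expected) and 1457 (1388 expected), and across 11788 genes, which are not independent replicates, the log2 changes correlated at r = -0.005 and 0.039. The 25 genes high in CF were as a set higher in SDF1 than in DF1 replicates 1 and 2 but lower in SCF than in CF. They are few among the 11788 genes, and the correlations were not computed without them. DF1 replicate 3, which lay far from the others, was included. METTL9, HSPB9, SPTB, SMOX and ADH1C rose most, by 2.00 to 2.78 in line 2 and 1.91 to 3.85 in line 4. TUBB3, S100A4, CSNK2B, GSTA3 and ATP8 fell most, with changes of -7.70 to -4.15 in line 2 and -8.07 to -3.38 in line 4. Of these, S100A4, CSNK2B, GSTA3 and ATP8 are among the 25 genes higher in every CF library than in every CEF and SCF library.

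Of 22 cholesterol synthesis genes, 1 rose and 15 fell in SCF2 against CF2, or 1 and 16 when adjusted over the list alone (camera adjusted p = 7.32e-05, but adjusted p = 0.122 with an estimated correlation). In SCF4 against CF4, 6 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.928), with a median of 0.03, or -0.12 after quantile normalization, while the camera test pointed down. DHCR7 changed by -0.86 and -0.55, STARD4 by -0.71 and -0.79 and SQLE by -0.69 and -0.40, and ACAT2 changed by -0.61 in line 2 and rose by 0.55 in line 4. Of 21 heat shock genes, 6 rose and 7 fell in line 2, also when adjusted over the list alone, and 10 rose and 4 fell in line 4, or 11 and 4 when adjusted over the list alone. The camera adjusted p was 0.419 and 0.305. HSPA2 rose by 0.33 and 1.38, HSPB1 changed by -1.08 and -1.34 and HSPA4 changed by -0.43 and -0.30. The SCF libraries were all in the first deposited set and the CF libraries in the second, so batch and group cannot be told apart.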

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

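All tests of technical explanations in this part were chosen after the result was seen, whereas the test of the difference between the lines was fixed before the data were examined.

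The change from primary culture to suspension line differed between line 4 and line 2 for 4905 genes in edgeR. Of 100 splits of the libraries, 1 gave as many, the real one, and the highest other gave 1955. The other splits mixed the lines within the primary and within the suspension libraries. Mixing puts the difference between the primary cultures into the spread within groups and lowers the count. Nothing about chance as the source of the interaction count follows from these splits. Of the 82 genes named for the suspension and primary cultures or for their difference, limma called the difference for 54. Part of the 82 had been named for a called difference or its small p-value, so their calls followed from that choice. Over all genes limma called the difference for 5099 of 13001. The values here are log2 changes in line 4 minus those in line 2. Among genes that rose in both lines the differences were CBLN2 (3.2), SKAP1 (1.7), APCDD1 (2.68) and MPZL2 (2.22). Among those that fell most in both they were LOX (-0.58), LSP1P1 (1.73), SPP1 (1.25) and FSCN1 (1.52). The largest differences by the fixed rule were PCBP4 (9.75), FGD5 (9.65), MYOD1 (9.62), NPY (9.43), MMP7 (9.19), PAPPA2 (-9.93), PITX1 (-9.41), SLC6A17 (-8.9), CSGALNACT1 (-8.15) and MATN3 (-8.12). Matrix and contractile genes gave COL12A1 (1.43), TGFBI (2.44), TAGLN (1.64), ACTA2 (2.71), TPM1 (1.6), CALD1 (-1.16), PDLIM3 (6.12), CRYAB (7.04) and DES (8.13). Adhesion, TGF-beta, lipase and cell cycle members gave ALCAM (-2.07), NCAM1 (2.43), LPL (2.03), FST (2.18), TGFB3 (1.34), KIF23 (-0.52) and PRC1 (-0.62). Cholesterol and unfolded protein response members gave INSIG1 (-2.58), HMGCS1 (-1.09), P4HB (-1.13), HERPUD1 (-1.48), DNAJB9 (-1.05) and HYOU1 (-0.95). Genes of immortalization and fat gave CDKN2A (-1.58), CDKN2B (-0.93), MKI67 (-1.38), MYC (-0.79), PPARG (1.79), PPARGC1A (4.11), FASN (-0.96), FABP4 (5.11) and PLIN2 (1.18), and matrix, adhesion and fibroblast genes gave COL1A1 (-0.9), FN1 (-1.16), CDH11 (8.03), VIM (-0.98) and CDH1 (2.48). The lines differ in breed label, culture and source, and which of these underlies the differences was not tested. For NPY, MMP7, MYOD1 and MATN3 the log2 changes in CEF4 against CEF2 were -9.29, -9.17, -8.13 and 8.12. The difference of these genes thus lay mostly between the primary cultures. The skeletal muscle and cartilage lists also went the opposite way in CEF4 against CEF2. PITX1 and PCBP4, in contrast, were read in both primary cultures and lost in line 4 alone and line 2 alone. Where a gene was near 0 in a group the size of the difference depends on the 1 added before the logarithm.

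In each of the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and only the real split, 1 of 10, gave as many called genes. The real count was 9457 in SCF2 against CEF2, 9509 in SCF4 against CEF4, 5563 in CEF4 against CEF2, 5667 in SDF1 against DF1, 9552 in FAT against CF4, 9473 in CF2 against CEF2, 9213 in CF4 against CEF4, 5713 in SCF2 against CF2 and 6002 in SCF4 against CF4. The highest other split gave 0 in each, with edgeR for the first 3 and limma for the rest. For the 6563 genes shared by the lines, 1 of 100 splits gave as many, the real one, and the highest other gave 0. These splits mixed primary and suspension libraries within a line. Such splits called no gene in either comparison, so the shared count could only be 0, and nothing about chance follows from it.

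DF1 replicate 3 stood apart from replicates 1 and 2. The tables argue against lower depth, since it had 17.2 M recovered reads against 17033022 and 16621605 reads in the others, a limit restated after a first run as fewer than both. They argue against an admixture of cells like replicates 1 and 2, since 18 genes at 100 or more in both of those were under 2 in replicate 3. They argue against a swap with a library of CF2, CF4, SCF2, SCF4 or SDF1, since its highest correlation across genes with one of these was 0.963 (CF2 replicate 2), below the lowest within those groups (0.99). That test replaced a first one based on a count of genes, which had come out exactly at its limit. Its correlation with DF1 replicates 1 and 2 was 0.95 to 0.952, lower than with CF2, so a single wrong label or a sample from outside the series stays open. Another library preparation or counting stays open too. ATP8 was 13.24% of ATP6 in replicate 3 and 1.1% and 1.22% in replicates 1 and 2, but its position between SCF (0) and CF (1) on the 25 genes of the next paragraph was 0.51, between both. The design names no difference among DF1 replicates, so no biological explanation was tested.

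In 25 genes every CF library was above 50 and more than 2 times every CEF and SCF library, among them S100A4, GSTA3, CSNK2B, ATP8 and VIP. CEF and SCF were in the first deposited set and CF in the second. Growth in suspension as the whole source is argued against, since SDF1, grown in suspension, had a median position of 0.75 between SCF at 0 and CF at 1. The second set as a whole is argued against as well, since 2 of its libraries, DF1 replicates 1 and 2 (0.17 and 0.11), lay under 0.25, while FAT lay at 1.04 to 1.14. A preparation shared by part of the second set stays open, and for CF against CEF or SCF it cannot be told apart from the group. The same holds for SDF1 against DF1, since ATP8 was 16.71 to 17.37% of ATP6 in SDF1 and the SDF1 libraries lay at 0.71 to 0.77. A difference of the CF cells themselves also stays open and was not tested.

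The source name and the breed field of SCF2 and SCF4 name opposite breeds. Of the genes that differed by a log2 of 4 or more between CF2 and CF4, 87.0% had the same sign between SCF2 and SCF4. That was 60 of 69 genes, with a 95% Wilson interval of 77 to 93%. This share argues against an exchange of SCF2 and SCF4 relative to CF2 and CF4, without a measure of its uncertainty between lines. The same test between CEF and CF cannot tell whether the lines match the primary culture of their number. There 43.6% kept their sign (48 of 110 genes, 34.7 to 53%). The genes of each test come from the same libraries and are not independent replicates. Both intervals treat them as independent, so they do not measure the uncertainty about an exchange or a match. In both tests genes under 2 in every library of the second pair were left out, a change made after the first values had been seen. Before it such genes counted as a change of sign, and the second test would have argued against a carried-over difference instead of leaving it open. The first test kept its outcome. Of the 50 genes most different between CEF2 and CEF4 and near 0 in one of them, all were higher in CEF2, and 39 had a mean under 2 in SCF2, 38 in SCF4, 40 in CF2 and 38 in CF4, so they do not tell the lines apart. Groups were not changed.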

How the results depend on the processing

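The alternatives were fixed before the data were examined, except edgeR on recovered reads and the block, quantile and leave-one-out settings for the gene lists and for the overlap, which were chosen after seeing them. Of 262 alternative values of the counts of genes and lists, 241 stayed within 1.5 times the reported count and 21 did not. Of 340 gene results, 307 kept their direction and their side of the threshold under every alternative run. Most of the 340 had been chosen from these data for large changes or small p-values, which favours a stable call. Apart from MATN3, CRYAB, DKK3 and PDZD2, the results that changed were of genes fixed beforehand. Of single alternatives for genes, 4372 gave the same call, 50 lost it, 23 gained one and 7 changed sign.

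Under quantile normalization the log2 change became 2.04 for TERT in SCF2 against CEF2, 1.10 for PPARGC1A in SCF2 against CEF2 and 0.59 for THY1 in SCF4 against CEF4. In FAT against CF4 it became -0.97 for TERT, -0.69 for THY1 and -0.62 for CDH1. Without FAT replicate 3, PPARGC1A was at -1.0 in FAT against CF4, and leaving out each library in turn gave -1.0 to 1.1. The cause was not tested.

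With only the groups compared, 3619 genes were called in SDF1 against DF1. Leaving out 1 library at a time gave 4646 to 8683 genes there, the highest without DF1 replicate 3. Leave-one-out counts in the other comparisons stayed within 1.5 times. With a log2 change of 1 or more also required, the lines shared 3719 genes.

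With an estimated correlation the lists called of 34 went from 20 to 11 in SCF2 against CEF2, 17 to 5 in SCF4 against CEF4, 11 to 5 for the line difference, 19 to 7 in CEF4 against CEF2, 18 to 1 in FAT against CF4 and 14 to 7 in CF4 against CEF4. They went to 0 with camera in SDF1 against DF1 (from 6; 4 at an unadjusted p under 0.05; 26 with fry), SCF2 against CF2 (from 8; 6 unadjusted; 25 with fry) and SCF4 against CF4 (from 7; 5 unadjusted; 22 with fry). With fry, which does not compare a list with other genes, 32 were called in SCF2 against CEF2, 32 in SCF4 against CEF4, 28 for the line difference, 30 in FAT against CF4, 33 in CF2 against CEF2 and 27 in CF4 against CEF4.

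With a replicate block the counts were 9168 in SCF2 against CEF2, 9226 in SCF4 against CEF4, 4531 for the line difference, 5162 in CEF4 against CEF2 and 6311 for the overlap. The replicate numbers do not pair libraries, so the block removes nothing known. FAT had the fewest recovered reads, 4.6 to 10.4 M, and 1 read there equals 1.521 to 3.162 normalized reads, which limits what can be read from low values in that group.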

Other observations

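The tests in this part were all chosen after the result was seen. Of 7432 genes at 100 or more in every CEF library, 197 were under 2 in every library of CF2, 173 in CF4, 184 in SCF2, 161 in SCF4, 99 in DF1 and 157 in SDF1. In all 6 groups together 77 genes were under 2 in every library, among them FBLN1, FIBIN, COL8A2, LPL, FST and NECTIN1. Of the 7432 genes, 126 were under 2 in all CF and SCF groups and 89 in both DF1 and SDF1. Loss at random in the CF and SCF lines on one side and DF1 and SDF1 on the other is argued against. The 77 shared compare with a mean of 1.71 and a highest of 8 in 10000 draws matched on the CEF level. The draws made all genes of a similar CEF level equally likely to be lost. They therefore cannot decide on separate losses that favour the same genes. This draw replaced one that treated all 6 groups as independent. Loss of these genes in the preparation of the second set is argued against too, since 68 of the 77 were at 10 or more in every FAT library. There 1 read equals 1.521 to 3.162 normalized reads, so 10 is only a few reads. That the SCF libraries of the first set lacked them follows from how the genes were chosen. A candidate explanation is a silencing of the same genes on immortalization, or a cell type of the primary cultures that none of the lines derives from, or a shared origin of the lines. These were not separated by any test here, and the 77 genes were found and tested on the same data.

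The W-linked gene UBE2R2L was 88.7 ± 116 in DF1, with a range of 18.5 to 222, and 483 ± 21.5 in SDF1. ATP5A1W was 491 ± 516 in DF1, with a range of 186 to 1090, and 2160 ± 63.8 in SDF1.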
